A study of Mus musculus with 1000 samples.

How the data were processed

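Brains without the cerebellum were collected from third-generation mice, usually between 8 and 12 weeks of age, and stored for up to 5 days before RNA extraction, per the labels' protocols. Typically 12 siblings of a pedigree were screened. Libraries were made with a 3′ cDNA kit from 4 ng of total RNA, with 8 cycles of cDNA amplification. A sequencing batch comprised 1152 libraries on 12 plates of 96 wells. Each sample in a plate row received its own in-line index, and the 12 samples of a row were pooled before the second library step, which gave 96 row pools per batch. A 3′ protocol samples the end of a transcript, so its reads measure gene abundance and cover little of the upstream coding sequence.

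The submitters' processing notes name GSNAP, a read aligner, and the genome build GRCm38. Software versions, the read counter, filters and normalization are not given in the sources used here. The deposited file analysed here was a lookup table with 3 columns, namely a row number, a library name and the label of a processed table. It had 23231 rows with no repeated library name and 3 different table labels. The label is text and has no unit or normalization. Rows were matched to samples by the whole title, and 1000 rows matched. The other 22231 rows name libraries outside the set described here and were not used. The processed expression tables themselves were not analysed here.

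The ENU pedigree number, animal number, plate, well and S number were read from the library names, with the digits after B6G3 taken as the animal number. Libraries were grouped only by the candidate gene or pedigree label. A row pool was defined as a plate and a well row. The S number took a single value in each of the 85 row pools. Counts were made with Python 3.11.15 and pandas 2.3.3, figures with matplotlib 3.10.9, and translation with Biopython 1.88. The Mast1 coordinates are 1-based and come from GENCODE release M21, which annotates the build named by the submitters. Coding sequence was taken from the matching transcript sequences, and residues were counted from 1 at the start codon.

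The tests, gene lists, rule for named genes and 8 of the 9 alternatives were fixed before the contents of the lookup table were examined. The library names and labels had been read by then, and showed that each labelled pedigree filled 1 row pool of 1 plate. It was also known that a lookup table was the only listed file, so the gene test might not be possible. The comparison of the label residues with the reference protein, and the alternative that used the shorter coding transcript, were added afterwards. The planned test of each gene between the 2 labelled pedigrees was not run, because the file holds no expression value. No marker list was measured, and no gene was named apart from the one in the labels. Every result is a count or an annotation, with no sampling error to report and no p-value. The alternatives that were tried changed how titles were matched, how pools were defined, which pedigrees were included, whether each animal was counted once and which coding transcript was used.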

Results

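The series covered 3′ RNA-seq libraries prepared from the brains of third-generation mice descended from founder males treated with N-ethyl-N-nitrosourea (ENU), a chemical mutagen that introduces point mutations across the genome. The founders were of the inbred C57BL/6NCrl strain and received 3 doses of 100 mg/kg. The screen was designed to find pedigrees with an abnormal inflammatory state in the brain and then to search exomes for the causal variant. A total of 1000 libraries were described, and the library names assigned them to 88 pedigrees and 999 animals. The labels placed 24 libraries in a group. Of these, 12 came from a pedigree labelled with the candidate change Mast1 V155L+R156C and 12 came from a pedigree labelled as unaffected. All other libraries carried no group and entered no comparison. The only file analysed here was a lookup table that named the processed expression table holding each library. It contained no read count or expression value. The depth of each library was therefore unknown, and no gene could be compared between the 2 pedigrees.

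The labelled candidate gene was Mast1, which encodes microtubule-associated serine/threonine kinase 1. In the GRCm38 annotation (GENCODE release M21) the gene, ENSMUSG00000053693.16, lay on the minus strand of chromosome 8 from 84911903 to 84937359. It had 6 annotated transcripts, of which 2 were protein-coding and 4 were retained-intron transcripts. The longer coding transcript, ENSMUST00000109741.8, was 4872 nt long in 26 exons and encoded 1570 residues. The shorter, ENSMUST00000119820.1, was 2078 nt long in 17 exons. The labels gave the changes at the level of the protein, and their unchanged residues were compared with the reference translation. The reference protein of both coding transcripts carried V155 and R156, valine and arginine, so both residues named in the label matched it. The changes replace them with leucine and cysteine.

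Both affected codons were located by counting residues along the annotated coding sequence, so they were exonic and coding by construction. In the longer transcript they lay in exon 5, which spanned 84929222 to 84929382 on chromosome 8. The codon of V155 was GTG at 84929245 to 84929247, and the codon of R156 was CGT at 84929242 to 84929244. Exon 5 of the shorter transcript held both codons at the same positions. The reference coding strand from 5 residues before V155 to 5 residues after R156 read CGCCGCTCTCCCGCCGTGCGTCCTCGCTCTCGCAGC, which occupied 84929227 to 84929262 without an intervening intron. No read or variant call was examined for either codon, and the sequence given is the reference allele.

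**Figure D1:**
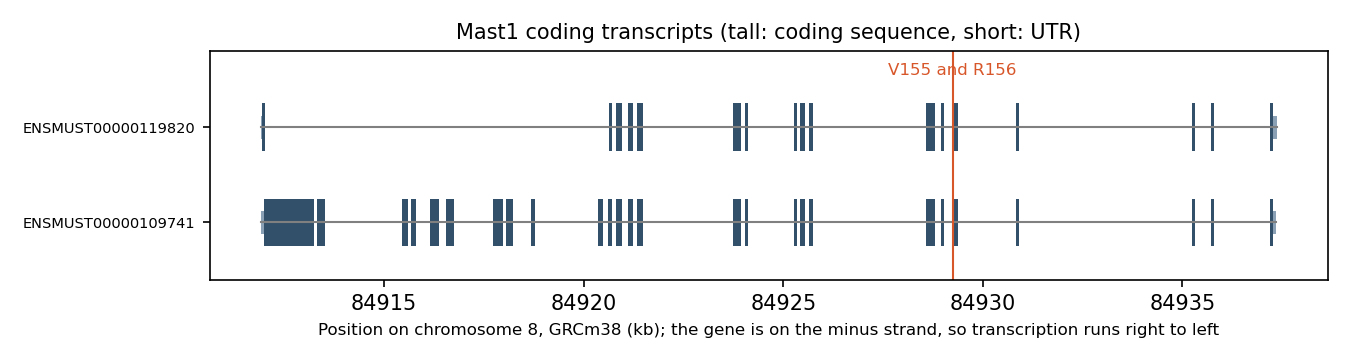
Exon structure of the 2 coding Mast1 transcripts along chromosome 8 (x axis, position in kb on GRCm38), with tall boxes for coding sequence, short boxes for untranslated regions and lines for introns. The vertical line marks V155 and R156, which lie in exon 5 of both transcripts.

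The comparison implied by the labels was between the brains of the Mast1 V155L+R156C pedigree and those of the unaffected pedigree. The Mast1 group consisted of 12 libraries from a single pedigree, ENU57047, with animal numbers between 1 and 13. The unaffected group consisted of 12 libraries from a single pedigree, ENU56351, with animal numbers between 1 and 21. Each group therefore held 12 relatives from 1 pedigree, and variation between pedigrees could not be estimated within either group. Within the Mast1 pedigree, the labels gave a genotype for 1 animal. This was animal 2, whose genotype was given as m/+ and whose primary phenotype (affected) was given as DAM, with histology block 7. Whether other animals had a phenotype label without a genotype was not examined. The genotypes of the other animals of the pedigree were not given in the labels, so carriers and non-carriers of the Mast1 changes could not be separated.

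The groups also differed in where their libraries were made. According to the protocol, the samples of a 12-well plate row were pooled after cDNA amplification and carried through library preparation together. All 12 Mast1 libraries occupied row G of plate neuro2161, and all 12 unaffected libraries occupied row D of plate neuro2169. Pedigree, row pool and plate thus divided these 24 libraries in the same way, and no batch term could separate them. In both groups the animal number rose along the row from column 1 to column 12. The lookup table placed all 24 libraries in the same processed table.

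Among the libraries examined, the 88 pedigrees were distributed over 85 row pools on 17 plates. Each of the 88 pedigrees fell within a single row pool in this set. A single pedigree was seen in 82 of the pools. The other 3 pools held 2 pedigrees each, so 6 pedigrees shared a pool with another pedigree among the libraries examined. Some of the pools with a single pedigree held fewer than 12 libraries here. Whether their remaining wells held other pedigrees was not examined. The median pedigree contributed 12 libraries. In the set described here there were 79 pedigrees with 12 libraries, 7 with 6 libraries, 1 with 8 and 1 with 2. Library names outside this set were not searched for these pedigrees, so the smaller counts may not be full pedigree sizes. The number of libraries per plate ranged from 12 to 96, and 4 plates had all 96 wells represented.

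**Figure D2:**
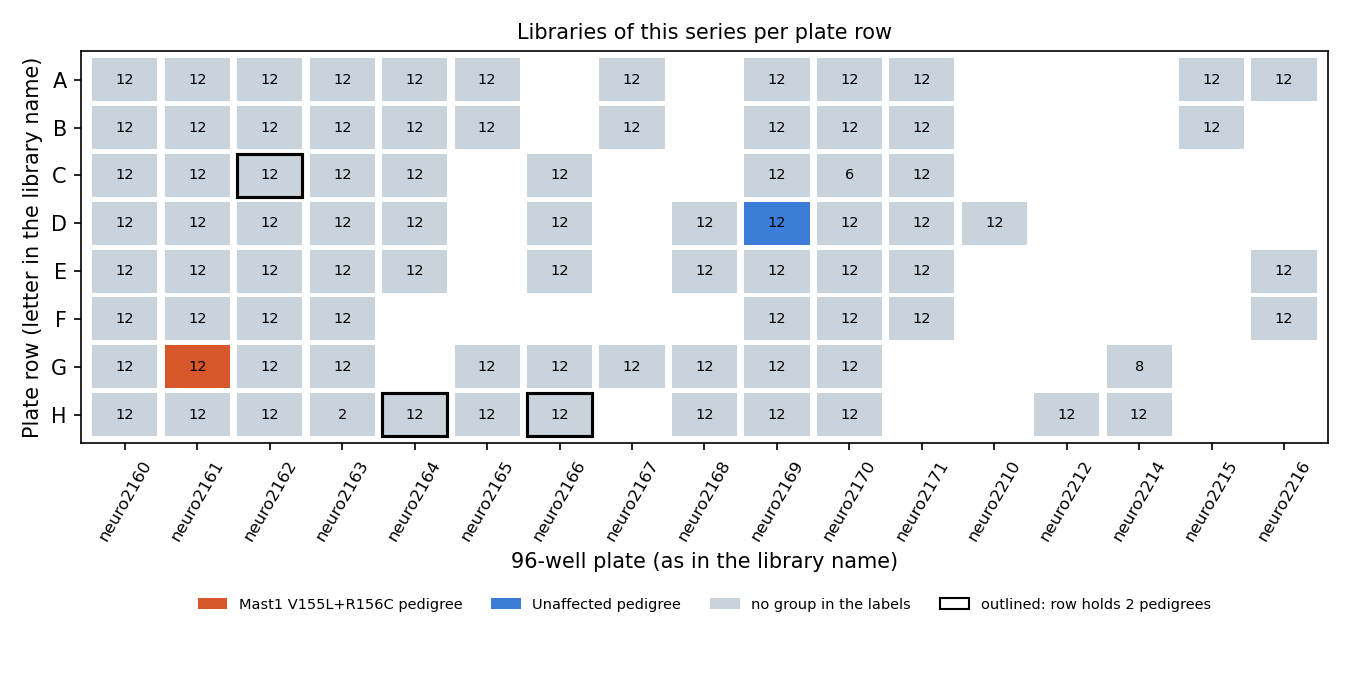
Number of libraries in each plate row (y axis, row letter) of each 96-well plate (x axis, plate name), with colours for the 2 labelled pedigrees and for libraries without a group. The Mast1 V155L+R156C pedigree fills row G of plate neuro2161 and the unaffected pedigree fills row D of plate neuro2169, each with 12 libraries, and the 3 outlined rows hold 2 pedigrees.

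All 1000 library names were found in the lookup table by exact match. Of these, 74.3% were assigned to the table named part1 and 25.7% to the table named part2. For 87 pedigrees the libraries were all in one table. The exception was pedigree ENU57111 on plate neuro2170, row H, with 9 libraries in part1 and 3 in part2. Plates were less uniform, and plate neuro2163, for example, had 24 libraries in part1 and 62 in part2.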

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

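In all, 6 counts were recomputed under 9 alternatives, of which 8 were fixed before the data were examined and 1 was chosen afterwards. None of the 9 moved a count by over 1.5 times, but most of them could not have done so and do not show that the counts are stable. The number of pedigrees held within a single row pool was 88 with pools defined by plate and S number and 88 for plates alone. Both values follow from the main count, since each row pool lies on one plate and had one S number. The count was 79 of 79 when only pedigrees with 12 libraries were included, which the main count of 88 had also fixed. All 1000 libraries also matched when the last number of the title was ignored or repeated rows were counted once, which the exact match of all 1000 and the absence of repeated names had already fixed. The median of 12 libraries per pedigree was the same when each animal was counted once, which removes 1 library. The alternative chosen afterwards used the shorter coding transcript of Mast1, in which both residues of the label matched. The other settings of the gene test (size factors, filter, pseudocount, block) were not run, since the test itself was not run. The median over all pedigrees of the lookup table was also not run, because libraries outside the set described here were not used. No paired analysis was possible because the file analysed holds no expression value and the replicate numbers of the 2 pedigrees only follow accession order. Library depth was unknown.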

Other observations

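The Mast1 label names changes in adjacent codons. From the reference codons, V155L can arise by a single base change in either of 2 ways, G463C (codon CTG) or G463T (codon TTG), and R156C by C466T (codon TGT), with positions counted on the coding strand from 1 at the start codon. The bases involved, at 84929247 and 84929244 on chromosome 8, are 3 bases apart. No single-base change gives both residues, and the labels do not state which base changes were found or whether they lie on the same chromosome copy. In the longer coding transcript the codon of R156 ends 4328 nt before the 3′ end of the spliced transcript, whose 3′ untranslated region is 83 nt long. The corresponding distance in the shorter coding transcript is 1528 nt. Whether any 3′ read covers these codons was not examined.

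One animal number occurs in 2 libraries. Animal 3 of pedigree ENU58267 is named in both column 2 and column 3 of row H on plate neuro2214. The same row holds animals 2, 4, 5 and 6 in columns 1, 4, 5 and 6, and columns 7 to 12 hold animals 8 to 13. Animals 1 and 7 do not occur in the row. Whether these libraries come from 1 animal or from 2 was not tested.

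Across the 82 row pools in which a single pedigree was seen among the libraries examined, the animal number rose with the column in 47. A rise was counted only where every number was above the one before it. Row H of plate neuro2214 was therefore not counted, because animal 3 is repeated there, although its numbers never fall. The number also rose with the column in the rows of the Mast1 and unaffected pedigrees, which are among these 47. The in-line index of each well was not read from any source used here.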
